A study of Arabidopsis thaliana with 2 samples.

How the data were processed

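The study measured gene expression in leaves of amiCOX17-1/cox17-2 plants (silenced) and of Col-0 wild-type plants. Per the labels, plants grew for 10 days on MS medium and 20 days on soil under 16 h light and 8 h dark at 23 °C, and 200 ng of RNA extracted with Trizol was labelled per sample. Each of the 2 arrays held silenced and WT RNA in opposite dyes, and the group and dye of each channel were taken from the labels.

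The spot intensities were deposited as scanned: per the file headers they are mean signals and median local backgrounds of the Cy5 and Cy3 channels from Agilent Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09, for an array design annotated on TAIR10. Agilent's processed intensities in the same files are background-subtracted and dye-normalized (linear and LOWESS), per the file headers. The log10 ratio per spot was deposited as the logarithm of processed Cy5 over processed Cy3, per the file headers, and served only to settle the direction of the authors' values. The flags for saturated, outlying and well-above-background spots are other columns of Feature Extraction, per the file headers. The authors' deposited value table holds log2 ratios for 43599 of the 43603 probes, and the submitters' processing notes name limma with no version. Its column medians were 0.0016 and 0.0007, and its correlation with the scanner's Cy5 over Cy3 ratio was 0.790 for replicate 1 and -0.842 for replicate 2, so both columns run as silenced over WT. The background correction and normalization behind it are not given in the sources used here.

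From the scanned signals, backgrounds were corrected with normexp (offset 50) and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 on R 4.3.3 (files read with the data.table package, version 1.17.8). The offset draws ratios of dim spots towards 0. Of 45220 spots, 1417 controls were left out, as were 20 outlier-flagged spots on the array of replicate 1 and 45 on that of replicate 2. Spots of a probe were averaged, and the ratio of replicate 2 was turned to silenced over WT. A probe was kept if it was well above background on both arrays in the channel of at least 1 genotype, which left 30248 probes. Probes were named through a table of RefSeq genes: 34348 by accession, 1627 by locus tag and 716 by symbol, while 6912 of the 43603 had no gene. Among kept probes 27619 had a gene and 2629 had none. A gene was represented by its probe with the highest mean intensity over both arrays, not by its change, giving 19523 genes, of which 13375 had a single kept probe.

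Differences were tested with limma (lmFit and eBayes, 2-sided, 1 residual degree of freedom per gene, prior degrees of freedom 37.6 and prior SD 0.165), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. With no more than 1 array per replicate number, no block could be fitted. The 2 arrays share a slide, so slide was not tested as a batch. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. These lists, the tests and the rule for named genes were fixed before the data were examined. That rule took every COX17 probe, the 12 largest increases and 12 largest decreases past the test with the same sign on both arrays, and in each list up to 4 members with the smallest p. A gene not well above background in a genotype on both arrays is given as at least N-fold, from channel values after loess and Aquantile scaling, with the dim channel set to the higher of its own value and the lowest value among probes well above background. The COX17 genes and the guard cell and phloem markers were too few to test as lists. No kept gene carried an ATMG or ATCG identifier, so organelle transcripts are given by the array's chromosome column.

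The alternatives tried were no background correction, an offset of 10, Agilent's processed signals, median in place of loess normalization, no filter and a strict filter on dim probes, the mean over a gene's probes, outlier-flagged spots kept, an intensity trend in the variance, the authors' deposited values, and each array alone. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15.

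The comparison of silenced with WT leaves was tested on simulated data: signals for the 19523 genes with 200 changed, noise at the prior SD and a dye curve to be removed. A first simulation used an invented dye curve, and after its false calls were seen a second was run with the curve loess removes from the real arrays. With the invented curve, 51 of 68 genes changed by 0.5 (log2), 66 of 66 changed by 1 and 66 of 66 changed by 2 were called, and 24 of 19323 unchanged genes were called, 11.6% of all calls. With the real curve the numbers were 49 of 68, 66 of 66 and 66 of 66, with 18 false calls, 9.05% of all calls. Both false shares lay above the threshold of 0.05. Changes of 0.5, 1 and 2 were estimated at medians of 0.45, 0.87 and 1.84 with the real curve. A lowered list of 34 genes was called by camera in both simulations and 0 of 20 unchanged lists were, but with an estimated correlation the lowered list was called in 0 of them. The simulated noise was alike for every gene, so this says nothing about genes with a larger spread. It was also drawn independently for each probe, so the simulated genes were not correlated. The list calls therefore do not test camera at the preset correlation where the members of a list vary together.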

Results

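Gene expression was compared between leaves of Arabidopsis thaliana plants with reduced COX17 function and leaves of wild-type (WT) Col-0 plants. COX17 is a small copper-binding protein that brings copper to the assembly of cytochrome c oxidase, the last complex of the mitochondrial respiratory chain, and Arabidopsis has 2 genes for it, COX17-1 and COX17-2. The silenced plants, amiCOX17-1/cox17-2, combined the cox17-2 mutation with an artificial microRNA against COX17-1. RNA came from shoots, given in the labels as leaves, of 30-day-old plants. Silenced and WT RNA were hybridised together on each of 2 two-colour Agilent arrays, given by the labels as biological replicates. Silenced RNA carried Cy5 on the array of replicate 1 and Cy3 on that of replicate 2, so the dyes were swapped. Nothing in the labels says how the plants were pooled, and p-values therefore rest only on the spread between these 2 arrays. That spread is mostly shared across genes (prior degrees of freedom 37.6 against 1 residual), so an SE says little about a single gene's own spread. The gene AT4G15680, at log2 ratios of 1.51 and 2.96 on the arrays, still had an SE of 0.16. The median spot signal on the array of replicate 1 was 336 in Cy5 and 79.7 in Cy3, against 106 and 28.7 for the negative controls. For replicate 2 these medians were 308 and 361, against 103 and 30.8. Of the spots that were not controls, 70.0% in Cy5 and 61.6% in Cy3 were well above background for replicate 1, and 69.8% and 71.8% for replicate 2. The dimmer Cy3 channel of replicate 1 held WT RNA. No spot was saturated (0 on either array), and the number of arrays limits the precision.

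The question the labels pose first is whether the targeted genes were lower in the silenced leaves. COX17-2 (AT1G53030) was 61.1-fold lower, with a log2 ratio of silenced over WT of -5.93 ± 0.12 (SE, n = 2 arrays, limma adjusted p = 4.42e-32). Its ratio was -5.70 for replicate 1 and -6.16 for replicate 2, the lowest of the 30248 probes kept. The size depended on how the dim silenced signal was treated, with -7.22 from Agilent's processed signals, -6.52 with an offset of 10 and -6.34 in the authors' deposited table. COX17-1 (AT3G15352) was lower by a smaller margin, 1.42-fold, with a log2 ratio of -0.51 ± 0.12 (SE, n = 2 arrays, limma adjusted p = 0.000422). This fall of COX17-1 was lost when the arrays were centred on their medians in place of loess normalization, where its log2 ratio was 0.06 (limma adjusted p = 0.880) and the median of all genes lay at 0.43.

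The COX17-2 probe behind that value is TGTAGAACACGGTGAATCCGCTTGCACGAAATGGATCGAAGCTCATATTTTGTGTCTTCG, placed by the array files on chromosome 1 at 19760246 to 19760305 (TAIR10). Its signal in silenced leaves was 163 for replicate 1 and 109 for replicate 2, over local backgrounds of 97.5 and 34.5, while WT leaves gave 1746 and 6729. A second probe named as COX17-2, designed on an expressed sequence tag and placed at 19761542 to 19761601 on the same chromosome, had a log2 ratio of 0.17 (adjusted p = 0.341 over all probes kept, limma). Averaging both probes gave COX17-2 a log2 ratio of -2.88. The COX17-1 probe that represents the gene lies on chromosome 3 at 5180430 to 5180489, and 32 of the 39 bases it can be aligned with in the COX17-2 probe are identical. A further COX17-1 probe at 5180567 to 5180626, which shares no such stretch, had a log2 ratio of -0.69 (adjusted p = 0.00184 over all probes kept, limma). Where these probes lie relative to exons and to the cox17-2 mutation was not analysed here, so none of them shows whether an intact transcript remained.

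**Figure D1:**
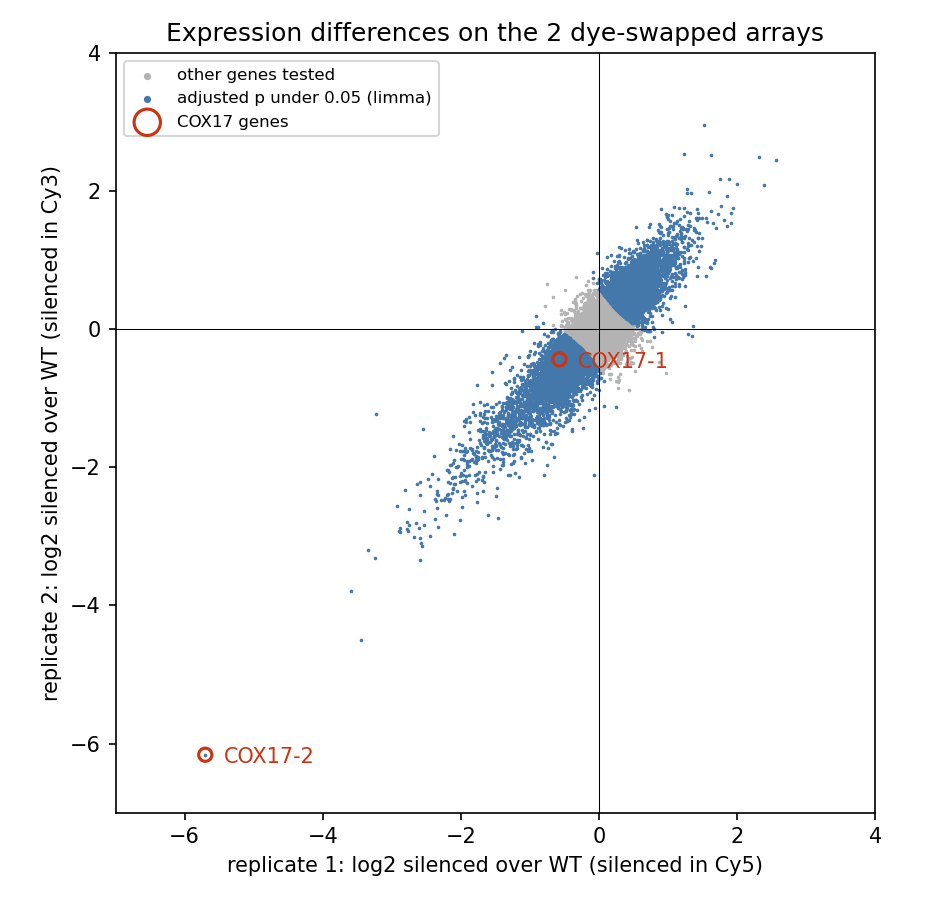
Each point is a gene, with its log2 ratio of silenced over WT on the array of replicate 1 (horizontal) and of replicate 2 (vertical), in blue where the limma adjusted p was under 0.05. The points follow the diagonal (Pearson r = 0.885 across 19523 genes), and COX17-2 lies apart at -5.70 and -6.16, while COX17-1, at -0.57 and -0.44, has a value above 0 after median normalization.

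Across the transcriptome, the genes that were most strongly higher in silenced leaves included BT2 (BTB and TAZ domain protein 2), at a log2 ratio of 2.51 ± 0.12 (SE, n = 2 arrays, limma adjusted p = 2.44e-20), or 5.69-fold. AT4G36850, a PQ-loop repeat protein, rose 5.29-fold and AT2G16660, annotated as a putative nodulin protein, 4.74-fold. Monothiol glutaredoxins, which are small redox proteins, were represented by AT4G15680 and AT4G15700. AT4G15680 was not well above background in WT leaves and was at least 4.72-fold higher in silenced leaves, and AT4G15700 rose by 2.03. The bound for AT4G15680 equals its fitted mean, with log2 ratios of 1.51 for replicate 1 and 2.96 for replicate 2. Members of this glutaredoxin cluster are near-identical, so their probes may share signal. Cell wall and extracellular proteins also stood among the 12 largest increases: the germin-like protein GER3 (2.06), the extensin family protein AT3G16670 (1.97), the xyloglucan endotransglucosylase XTH16 (1.89) and the pectinesterase ATPMEPCRB (1.80). MIOX2, an inositol oxygenase, rose by 2.07 with WT signal well above background on 1 array. DIN11, a 2-oxoglutarate-dependent oxygenase, was at least 3.69-fold higher, with no WT signal well above background, a bound that again equals the fitted mean of 1.23 for replicate 1 and 2.53 for replicate 2. AT4G22513, a lipid-transfer-like protein, rose by 1.85. No list was fixed beforehand for the cell wall and extracellular proteins named here, and lipid-transfer-like proteins stood among the largest decreases too.

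The largest decreases after COX17-2 were found for AT4G12490, a lipid-transfer-like protein with near-identical neighbours, at -3.97 (15.7-fold lower), and for the glutathione S-transferase GSTU25, at -3.69 ± 0.12 (SE, n = 2 arrays, limma adjusted p = 2.87e-25, 12.9-fold lower). GSTU8, of the same family of detoxifying enzymes, had a log2 ratio of -2.91. CAX3, a vacuolar cation/proton exchanger, was at -2.91, the lipid-transfer protein LTP4 at -2.85, and ELI3-2, annotated as cinnamyl alcohol dehydrogenase 8, at -2.85. The putative membrane lipoprotein AT3G18250 was at -3.28, the carbohydrate-binding X8 domain protein AT5G63225 at -3.26 and the hydrolase AT1G68620 at -2.88. Among uncharacterized proteins, AT1G58225 was at -2.84 and AT5G39520 at -2.97, with a further probe of AT5G39520 at -0.93. Near-identical gene copies make single values in such clusters uncertain.

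**Figure D2:**
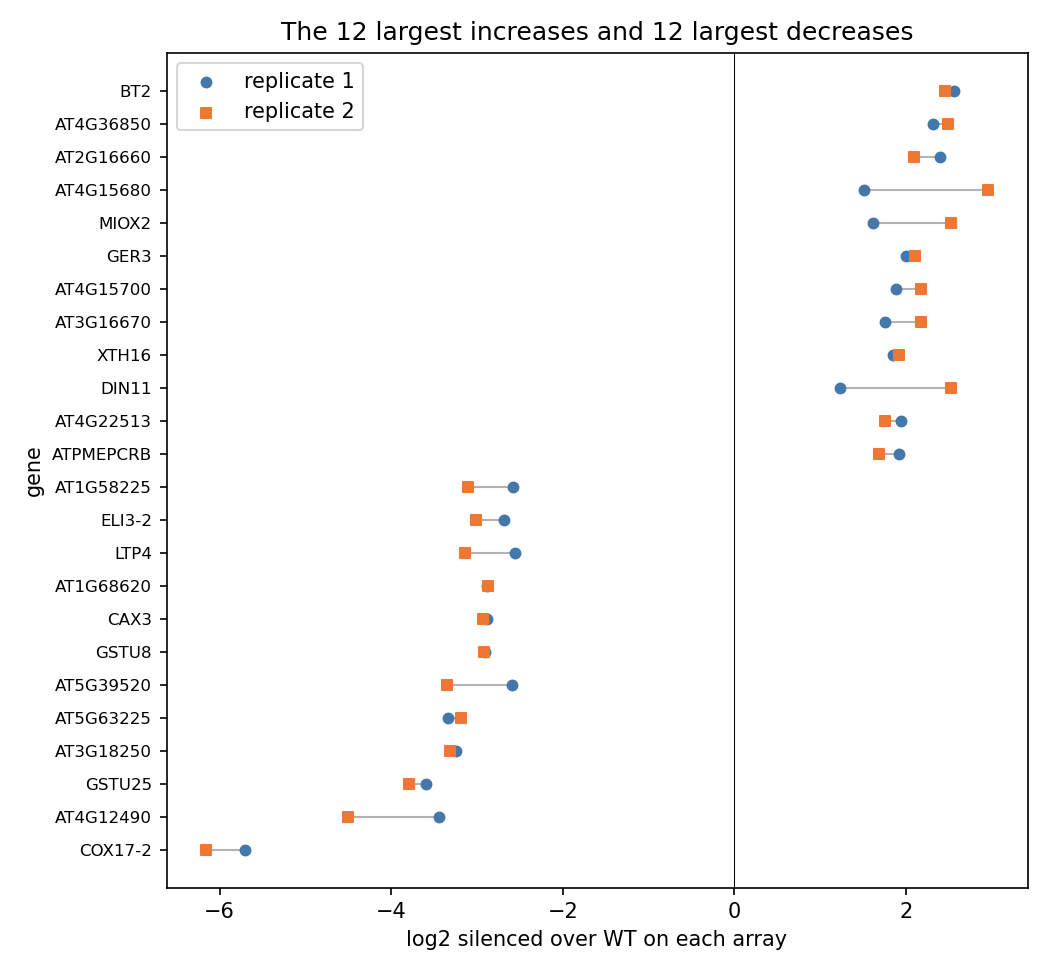
Log2 ratio of silenced over WT on each array (circles, replicate 1; squares, replicate 2) for the 12 genes with the largest increase and the 12 with the largest decrease among genes past the limma test. The means run from 2.51 for BT2 to -5.93 for COX17-2, and the rule for choosing these genes required the same sign on both arrays.

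Of 19523 genes tested, 9209 (47.2%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), with 4608 higher and 4601 lower in silenced leaves. Among genes past the test 268 were at least 2-fold higher and 728 at least 2-fold lower. On both arrays alike, 165 genes were at least 2-fold higher and 578 at least 2-fold lower, while 0 genes were at least 2-fold apart in the direction of the dye. The 2 arrays gave the same sign for 81.9% of genes, with a Pearson correlation of 0.885 and a Spearman correlation of 0.835 across genes, which are not independent replicates. At least 2-fold changes on both arrays numbered 1057 higher and 272 lower after median normalization, and 915 and 825 with Agilent's processed signals. The split of directions thus depended on the scaling, and 88.3% of the genes past the test were higher after median normalization and 64.1% with Agilent's processed signals, against the nearly even counts given above. In addition, each gene has 1 residual degree of freedom and borrows its spread from all others, so many small differences pass. Probes for ribosomal RNA, chosen after their values were seen, were measured as a sign of RNA content. Of 11 outside the mitochondrial genome 0 rose, 7 fell and 4 did not pass, with a median of -0.92, or -0.22 after median normalization. All 3 mitochondrial ones fell (median -1.24). Those of the 11 at a mean log2 intensity of 17.0 to 17.8 spanned -2.23 to -0.92. The dimmer ones, at 10.2 to 16.3, spanned -0.46 to 0.22. Intensity was not tested for this set, so it cannot be told apart from RNA content here.

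Genes of the mitochondrial stress response, which is switched on when respiration is disturbed, were lower in silenced leaves. Of 25 measured members 0 rose, 24 fell and 1 (SOT12, -0.26) did not pass, and 25 fell when adjusted over the list alone. GSTU25 led, followed by GSTU24 at -1.99 ± 0.12 (SE), the alternative oxidase AOX1D at -1.95 and the transcription factor WRKY40 at -1.89. AOX1A, the alternative oxidase gene most used as a marker of this response, was at -1.29 (limma adjusted p = 1.25e-11) and was chosen after its values were seen. The median of the list was -1.12, or -0.50 after median normalization (camera adjusted p = 8.50e-18, and adjusted p = 0.357 with an estimated correlation).

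Nuclear genes for cytochrome c oxidase subunits and assembly factors, where COX17 acts, were slightly lower as a group. Among 21 measured, 2 rose, 10 fell and 9 did not pass, and 2 rose and 11 fell when adjusted over the list alone. The assembly factor PET191 was at -0.79, COX6B-2 at -0.75 and COX19-2 at -0.50, the last turning to 0.09 after median normalization, while COX5B-1 rose by 0.58 and COX6B-1, chosen after its values were seen, by 0.34. The list median of -0.27 passed (camera adjusted p = 0.0375, and adjusted p = 0.461 with an estimated correlation), but after median normalization it was 0.30 and did not pass (camera adjusted p = 0.817). The other nuclear respiratory chain subunits did not pass as a list except in 1 of 11 settings, with an adjusted p of 0.0134 (median 0.16 in the fit used here, or 0.80 after median normalization, camera adjusted p = 0.162, and adjusted p = 0.684 with an estimated correlation). Of their 27 measured members 11 rose, 3 fell and 13 did not pass, with the same 11 and 3 when adjusted over the list alone. RISP1 (0.54), ATPB2 (0.52) and ATPO (0.49) rose, QCR7-2 fell to -1.02, and RISP2 and SDH2-2, chosen after their values were seen, were at -0.41 and -0.36.

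Salicylic acid and pathogen defence genes fell together. Of 27 measured, 1 rose, 19 fell and 7 did not pass, with 1 and 20 when adjusted over the list alone. The pathogenesis-related glucanase PR2 was at -2.57, the salicylic acid hydroxylase DLO1 at -2.02, the receptor kinase FRK1 at -1.93 and FMO1 at -1.86, while WRKY18, chosen after its values were seen, rose by 0.82. The median was -0.52 (camera adjusted p = 3.92e-09, and adjusted p = 0.357 with an estimated correlation), and it was -0.12 after median normalization. Oxidative stress genes fell as well: of 19 measured, 0 rose, 16 fell and 3 did not pass, and 0 and 16 when adjusted over the list alone. BAP1 was at -2.25 and the zinc finger factors ZAT10 and ZAT12 were at -2.12 and -2.03, with ERF5 at -1.79. GSTF8 (-0.22), RBOHD (-0.17) and RBOHF (0.21), chosen after their values were seen, did not pass. Their median was -0.78 (camera adjusted p = 6.57e-10, and adjusted p = 0.357 with an estimated correlation), and it was -0.23 after median normalization.

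Senescence and sugar starvation genes had the lowest median of the fixed lists, -1.17 (camera adjusted p = 6.57e-10, and adjusted p = 0.357 with an estimated correlation). It was -1.04 after median normalization and -1.77 with Agilent's processed signals. Of 14 measured, 1 rose, 12 fell and 1 did not pass, and the counts were 1 and 12 when adjusted over the list alone. The senescence regulators NAP and ORE1 were at -2.40 and -2.20, SAG13 at -2.25 and DIN2 at -1.95, whereas ASN1, which encodes an asparagine synthetase, rose by 0.51 and SWEET15 did not pass (-0.11), both chosen after their values were seen. Clock genes moved beside these groups: CCA1, which peaks in the morning, was at -0.94, and the like gene LHY was at -1.08 for replicate 1 and -0.92 for replicate 2.

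Several gene families linked to defence and detoxification were lower too, although their medians lay at or slightly above 0 after median normalization. The WRKY, glutathione S-transferase and cytochrome P450 lists share members with other lists given here, such as WRKY40, GSTU25, GSTF8 and CYP79B3. They are therefore not separate evidence. Among 51 WRKY transcription factors 4 rose, 26 fell and 21 did not pass, with 4 and 26 when adjusted over the list alone, and the median was -0.27, or -0.01 after median normalization. That shift passed (camera adjusted p = 4.64e-05, and adjusted p = 0.357 with an estimated correlation), with WRKY40, WRKY45 (-1.75), WRKY75 (-1.62) and WRKY50 (-1.32) leading. The risers were WRKY29 (0.83), WRKY18, WRKY57 (0.57) and WRKY13 (0.34), chosen after their values were seen. Of 40 glutathione S-transferases 3 rose, 23 fell and 14 did not pass, again 3 and 23 when adjusted over the list alone, and the median of -0.37 turned to 0.03 after median normalization. Their test gave a camera adjusted p of 1.12e-07, and adjusted p = 0.357 with an estimated correlation. GSTU3 was at -2.42 beside GSTU25, GSTU8 and GSTU24, and the risers, chosen after their values were seen, were GSTU26 (0.62), GSTU20 (0.50) and GSTU6 (0.31). Cysteine-rich receptor-like kinases showed 3 rising, 17 falling and 10 not past of 30, with 3 and 17 when adjusted over the list alone, and a median of -0.32 that turned to 0.04 after median normalization. CRK7 (-2.06), CRK6 (-2.05), CRK8 (-1.83) and CRK36 (-1.47) were the clearest, and CRK41, CRK42 and CRK30, chosen after their values were seen, rose (camera adjusted p = 0.000148, and adjusted p = 0.357 with an estimated correlation). For 138 cytochrome P450 genes 20 rose, 60 fell and 58 did not pass, with 20 and 61 when adjusted over the list alone, and the median of -0.21 turned to 0.05 after median normalization. CYP89A9 was at -1.63 and CYP81D11, CYP71B4 and CYP71B23 were at -1.53 (camera adjusted p = 0.000730, and adjusted p = 0.357 with an estimated correlation).

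Genes of anthocyanin and flavonoid synthesis fell: of 13 measured, 0 rose, 10 fell and 3 did not pass, with 0 and 10 when adjusted over the list alone. The regulator PAP1 was at -2.07, UF3GT at -0.94 and F3H at -0.91, and PAP2, not well above background in silenced leaves, was at least 2.59-fold lower. LDOX (-0.18), TT8 (-0.14) and PAL1 (-0.13), chosen after their values were seen, did not pass. The median was -0.63, or -0.17 after median normalization (camera adjusted p = 9.93e-06, and adjusted p = 0.357 with an estimated correlation). Glucosinolate and camalexin genes were lower in the fit used here, with 1 rising, 10 falling and 10 not past of 21, and 1 and 11 when adjusted over the list alone. CYP71A12, of camalexin synthesis, was at -1.40 and MYB51 at -1.18, CYP79B3 (-0.57) and CYP83B1 (-0.55) turned to 0.06 and 0.09 after median normalization, and MYB34, chosen after its values were seen, rose by 0.49. The list median of -0.26 (camera adjusted p = 0.0211, and adjusted p = 0.461 with an estimated correlation) became 0.28 after median normalization and did not pass there (camera adjusted p = 0.251).

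Hormone and heat lists held members of both directions and did not pass in the fit used here, although the abscisic acid list passed in 4 of 11 settings (lowest camera adjusted p = 0.0129) and the jasmonate list in 1 (0.0224). Jasmonate and wounding genes had 10 rising, 4 falling and 12 not past of 26, and 10 and 4 when adjusted over the list alone. JAZ10 rose by 1.56 and THI2.1 by 0.90, while ERF1 was at -1.84, ORA59 at -0.93, and MYC2 and AOC1, chosen after their values were seen, at -0.66 and -0.41 (median 0.17, or 0.72 after median normalization, camera adjusted p = 0.165, and adjusted p = 0.645 with an estimated correlation). Abscisic acid, drought and cold genes had 7 rising, 12 falling and 6 not past of 25, and the same 7 and 12 when adjusted over the list alone. GOLS2 was at -2.32, CBF2 at -1.93, CBF1 at -1.70 and DREB2A at -1.20 (median -0.17, or 0.19 after median normalization, camera adjusted p = 0.0515, and adjusted p = 0.461 with an estimated correlation). Of 8 auxin response genes 2 rose (IAA19, 0.82, and IAA5, 0.34), 1 fell (GH3.3, -0.32, or 0.25 after median normalization) and 5 did not pass, ACS4 at 0.18 among them. Adjusted over the list alone the counts were 2 and 1 (median 0.11, or 0.49 after median normalization, camera adjusted p = 0.453, and adjusted p = 0.684 with an estimated correlation). Among 9 heat shock and unfolded protein genes 3 rose, 4 fell and 2 did not pass, with 3 and 4 when adjusted over the list alone. BIP3, a chaperone of the endoplasmic reticulum, was at -2.01 and HSP70-4 at -0.91, while HSP18.2 rose by 0.73 and HSFA3 by 0.72. Chosen after their values were seen, ROF1 rose by 0.58, and HSFA7A and HSP90.1 were at -0.55 and -0.42 (median -0.23, or 0.13 after median normalization, camera adjusted p = 0.433, and adjusted p = 0.766 with an estimated correlation).

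Copper homeostasis genes, of interest because COX17 carries copper, had 4 rising, 14 falling and 7 not past of 25, the same 4 and 14 when adjusted over the list alone. The copper/zinc superoxide dismutase CSD1 was at -0.76, the copper transporters COPT1 and COPT2 were at -0.70 and -0.62, and the reductase gene FRO4 was at -0.83 (-0.24 for replicate 1 and -1.43 for replicate 2). ARPN (0.53), FSD1 (0.38), PAA2 (0.36) and PAA1 (0.34) rose and were chosen after their values were seen. The list did not pass in the fit used here but passed in 3 of 11 settings, with a lowest adjusted p of 0.0273 (median -0.31, or 0.24 after median normalization, camera adjusted p = 0.0515, and adjusted p = 0.684 with an estimated correlation). Iron homeostasis genes had 4 rising, 7 falling and 7 not past of 18, with 4 and 7 when adjusted over the list alone. The iron store protein gene FER1 was at -1.37, NAS3 at -1.30, BHLH101 at -0.89 and PYE at -0.81, and IMA2, IMA1, NAS1 and FER3, chosen after their values were seen, rose by 0.54, 0.52, 0.50 and 0.46 (median -0.06, or 0.11 after median normalization, camera adjusted p = 0.332, and adjusted p = 0.684 with an estimated correlation). Photosynthesis genes had 3 rising, 11 falling and 28 not past of 42, with 3 and 11 when adjusted over the list alone, and their list median was 0.12 for replicate 1 and -0.46 for replicate 2. LHCB1.5 was at -0.67, and LHCB1.4 (-0.60), LHCB2.4 (-0.56) and LHCB4.2 (-0.55) turned to 0.07, 0.10 and 0.10 after median normalization. The small subunit genes RBCS3B (0.63), RBCS2B (0.61) and RBCS1B (0.34), chosen after their values were seen, passed on the mean of the arrays but were at 1.35, 1.29 and 0.79 for replicate 1 and at -0.09, -0.07 and -0.11 for replicate 2, and both families hold near-identical copies (median -0.16, or 0.50 after median normalization, camera adjusted p = 0.157, and adjusted p = 0.842 with an estimated correlation).

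Ribosomal protein genes were the list that rose. Of 342 measured, 238 rose, 19 fell and 85 did not pass, with 244 and 21 when adjusted over the list alone, and the median was 0.44, or 1.06 after median normalization (camera adjusted p = 1.03e-16, and adjusted p = 0.357 with an estimated correlation). RPS6, of the small cytosolic subunit, rose by 1.32 and AT1G23410, a 40S protein, by 1.32. AT2G07725 (-1.51) and AT2G07675 (-1.47), the clearest decreases, lie in the region of chromosome 2 that carries a copy of mitochondrial DNA. The rule for the list was meant for cytosolic proteins, and by description it also took in proteins of 50S and 30S type.

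Markers of the time of day and of other organs and cell types were measured in the same leaves. Among 15 clock genes 3 rose, 5 fell and 7 did not pass, with 4 and 5 when adjusted over the list alone. RVE1 (-1.10), LHY and CCA1 (-0.94) fell and LUX rose by 0.77. Chosen after their values were seen, PRR3 (0.47) and TOC1 (0.36) rose, and ELF4 (-0.43) and FKF1 (-0.28) fell (list median -0.02, or 0.62 after median normalization, camera adjusted p = 0.551, and adjusted p = 0.727 with an estimated correlation). Flower and floral transition genes had 2 rising, 4 falling and 5 not past of 11, with 2 and 4 when adjusted over the list alone. SEP1 was at -1.02 and FT at -0.76, SOC1 (-0.50) and FUL (-0.51) turned to 0.14 and 0.06 after median normalization, and AP1 and AP3, chosen after their values were seen, rose by 0.30. Their median was 0.01 (-0.11 after median normalization, where the list passed, camera adjusted p = 0.0213) while their mean was -0.18 and the test pointed down (camera adjusted p = 0.346, and adjusted p = 0.684 with an estimated correlation). Xylem and secondary wall markers had 3 rising (XCP1, 0.83, XCP2, 0.67, and LAC17, 0.49), 4 falling and 5 not past of 12, with 3 and 4 when adjusted over the list alone. SND1, not well above background in silenced leaves, was at least 1.90-fold lower, and CESA8, CESA7 and FLA11 were at -0.33, -0.29 and -0.28, chosen after their values were seen. Their median was -0.02 (0.27 after median normalization) and their mean 0.01, with the test pointing up (camera adjusted p = 0.831, and adjusted p = 0.938 with an estimated correlation). Root markers had 0 rising, 0 falling and 5 not past of 5, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.830, and adjusted p = 0.872 with an estimated correlation), and passed in 1 of 10 settings, median normalization (-0.43, camera adjusted p = 0.0224), with CASP2 at -0.14, SHR at -0.09 and CASP1 at -0.05, and COBL9, not well above background in WT leaves, given as at least 1.03-fold and not past the limma test. The guard cell and phloem markers MYB60 (0.21), SUC2 (-0.20), FAMA (0.11) and KAT1 (0.03) were too few to test and none passed the limma test.

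**Figure D3:**
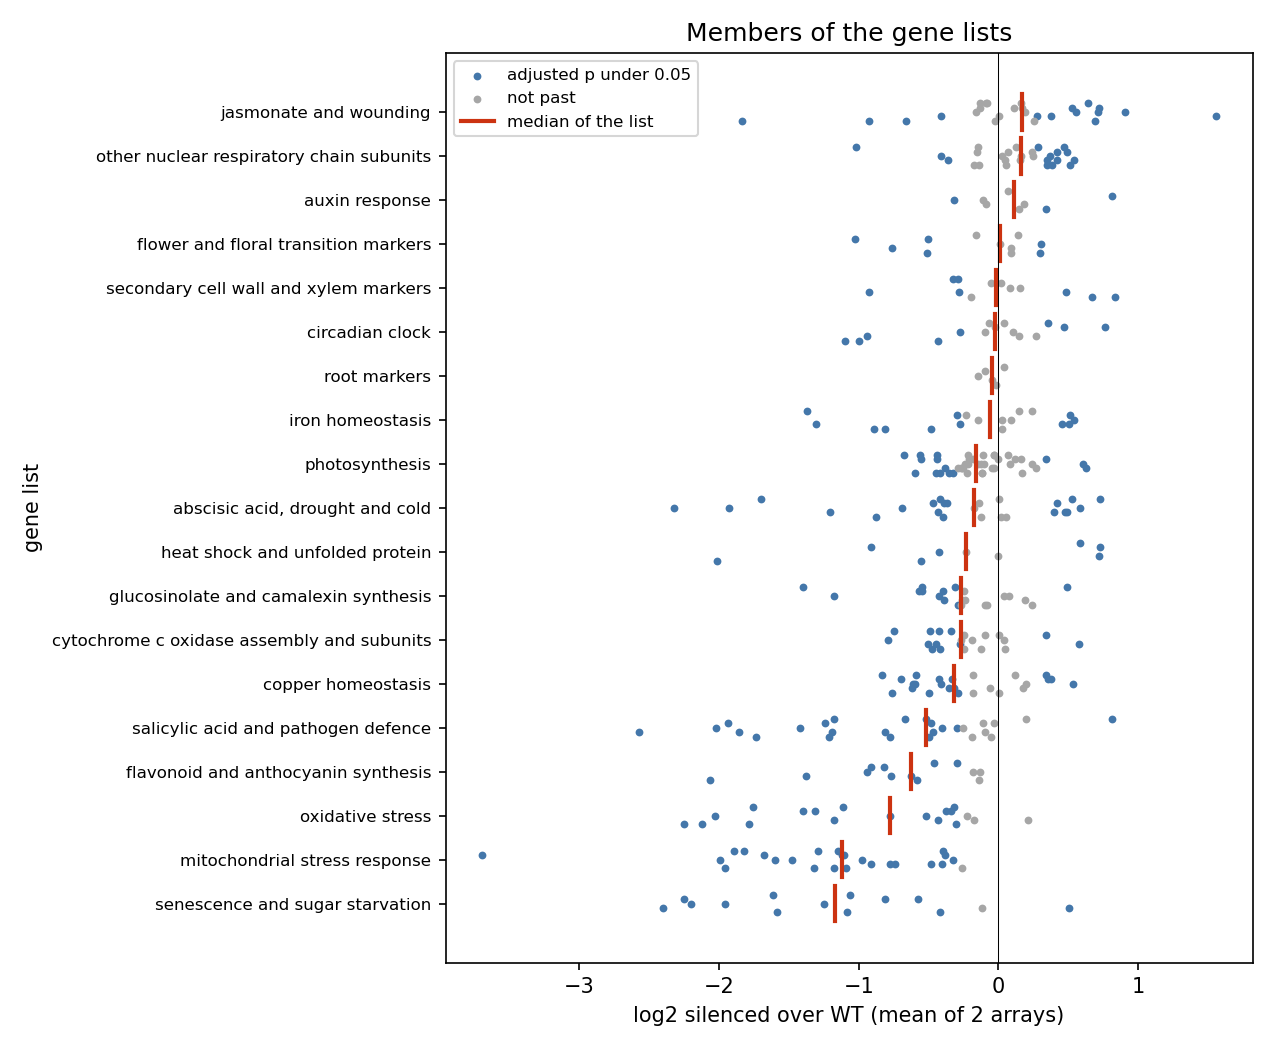
Each point is a member of a list written before the data were examined, with its log2 ratio of silenced over WT (mean of 2 arrays) on the horizontal axis, blue where the limma adjusted p was under 0.05, and a red line at the median of each list. The lowest medians belong to senescence (-1.17), mitochondrial stress (-1.12) and oxidative stress (-0.78), while several medians near 0, such as those of the cytochrome c oxidase (-0.27), copper (-0.31), glucosinolate (-0.26) and photosynthesis (-0.16) lists, are above 0 after median normalization.

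In all, 12 of 24 tested lists passed camera with a preset correlation, 11 lower and 1 higher, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.357. Several of the lower lists share members, so their count is not one of independent results. Camera with an estimated correlation rests on 1 residual degree of freedom and missed the lowered list in both simulations. Not passing it therefore decides little about a list. The simulations held no correlation between genes, so they do not back the calls at the preset correlation for lists whose members vary together. With limma's fry, which asks whether the genes of a list move on balance one way, the mitochondrial stress, oxidative stress and cysteine-rich receptor-like kinase lists passed (3 of 24, adjusted p = 0.0477 each), and 17 of 24 passed its test for change in either direction.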

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

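For this part, the tests of dye bias, of harvest time, of normalization for the stress lists, of organelle labelling and of ribosomal RNA were chosen only after the result was seen, while the tests on ribosomal protein genes and the intensity test on mitochondrial probes were written before.

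Transcripts of the mitochondrial genome, which the gene lists did not reach, drew attention because 25 of 85 probes were at least 2-fold apart on both arrays in the direction of genotype and 0 in that of dye, with 0 higher, 67 lower and 18 not past the limma test (median log2 ratio -0.80). Of 10000 random probe sets matched on intensity, 0% reached that median (their medians spanned -0.17 to 0.25), so the mitochondrial probes lay below other probes of like intensity. Loess had already removed the trend with intensity on each array, which puts such sets near 0 beforehand. A bias with intensity is therefore not decided by them. Weaker labelling of all organelle RNA alike stays open. The gap to the plastid probes (mitochondrial minus plastid median -0.53 and -0.48 on the arrays) lay within the spread of those probes (SD 0.786 and 0.829). That SD describes single probes and not a median, so this comparison cannot decide the question. The plastid probes went both ways, with 13 higher, 37 lower and 44 not past. Probes for ribosomal RNA outside the mitochondrial genome had a median of -0.75 on the array nearer 0 and -1.09 on the other. Over both it was -0.92, but -0.22 after median normalization and -0.09 with no filter. By placement or description it was -0.46 for 7 plastid and -1.55 for 4 other probes. The brighter of these probes fell furthest, and intensity was not tested for them. A difference in the content of ribosomal or other non-polyadenylated RNA between the samples stays open, not told apart from a bias with intensity. A lower level of mitochondrial RNA in silenced leaves stays open beside it, since the 82 mitochondrial probes not named as ribosomal RNA had a median of -0.78, with nuclear copies of mitochondrial DNA and differences in growth or handling not tested. The mitochondrial medians of -0.80 and -0.78 come from the loess fit, and their values after median normalization are not given here. There the plastid median turned from -0.28 to 0.37, so the size of the mitochondrial fall against 0 may rest partly on the scaling.

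Plastid genome probes were at least 2-fold apart on both arrays in the direction of genotype for 16 of 94, with 13 higher, 37 lower and 44 not past, and their median of -0.28 turned to 0.37 after median normalization. Probes with no gene gave 149 such probes of 2629, with 356 higher, 655 lower and 1618 not past. Of the ribosomal RNA probes, chosen after their values were seen, the 2 for nuclear 18S were at -2.23 and -1.50 (the latter -0.40 for replicate 1 and -2.60 for replicate 2), and the 5 for plastid 16S spanned -2.19 to 0.22, with 2 lower and 3 not past the limma test.

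The lower mitochondrial stress, oxidative stress, salicylic acid and senescence lists were weighed against dye bias, normalization and harvest time. Dye bias is argued against by the swap itself, since a dye effect alike on both arrays cancels in their mean. Of the members, 2.35% (2 of 85) had opposite signs on the arrays. Lists taken up for being lower on that mean leave little room for opposite signs, so this share adds little. Normalization alone is argued against for the mitochondrial stress and senescence lists, whose medians stayed at or below -0.50 under every background, signal and normalization alternative. For the salicylic acid and oxidative stress lists the highest median, -0.12, lay above the bound of -0.25 (a bound first written for the 4 lists together, which would have come out for normalization, and divided after the result was seen), but it came from median normalization, where the median of all genes was 0.43. Relative to the median of all genes the higher of these lists was at -0.53 in the fit reported, and the highest value under such an alternative was -0.55, while both passed camera in all 11 settings (highest adjusted p = 4.46e-07, but adjusted p = 0.357 with an estimated correlation in the fit reported), so normalization is argued against as the reason they lay below other genes, while the size of their fall against 0 depends on the scaling. Harvest at another time of day stays open, since the median of 4 morning clock genes lay below that of 7 evening clock genes by more than 1 (log2) on both arrays (morning minus evening -1.09 on the array nearer 0), as do the genotype itself and differences in growth or handling, which were not tested.

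The higher ribosomal protein list may reflect genotype, and normalization is argued against as the reason it lay above other genes. Of 10000 random lists matched on intensity, 0% reached the median of 0.44 (their medians spanned -0.16 to 0.06), so the list lay above other genes of like intensity. Loess had already removed the trend with intensity, so these lists lie near 0 beforehand and cannot decide a bias with intensity. Normalization would need the list's median to vanish under another scaling, and its lowest value over the background, signal and normalization alternatives was 0.44. Those alternatives put the median of all genes between 0.01 and 0.43, so a higher list could hardly vanish against 0. Relative to the median of all genes, the list was at 0.426 in the fit reported, and its lowest value under such an alternative was 0.428. A difference in growth stage or harvest time was not tested for this list.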

How the results depend on the processing

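The alternatives for lists and ribosomal RNA probes chosen later were added after the data were seen; the others were planned. No paired analysis was possible because each replicate number is a single array that already holds both genotypes, and with 1 array left counts and list tests could not be computed. The count of genes past the limma test was within 1.5 times of 9209 under all alternatives, from 6937 (median normalization, 4567 of them shared) to 10557 (adjusted p under 0.1). The median of all genes was 0.01 in the fit reported, 0.12 with Agilent's processed signals and 0.43 after median normalization. Against that shift, the cytochrome P450, glutathione S-transferase and cysteine-rich receptor-like kinase lists, with medians of 0.052, 0.030 and 0.043, still passed as lower than other genes (adjusted p = 0.357 each with an estimated correlation in the fit reported). Lower genes numbered 2682 with Agilent's processed signals and 812 after median normalization. Genes at least 2-fold apart on both arrays numbered 1740 and 1329 in these settings, and in the dye direction 10 and 4. Genes at least 2-fold higher numbered 288 with an offset of 10, 915 with Agilent's processed signals, 1057 after median normalization and 262 with the authors' deposited values, and those at least 2-fold lower numbered 825 with Agilent's processed signals and 272 after median normalization, where the correlation of the arrays was 0.706. Signs turned after median normalization for COX17-1 (0.055, limma adjusted p = 0.880, against 1.81e-06 to 0.0417 elsewhere), COX19-2 (0.089), LHCB2.4 (0.10), LHCB4.2 (0.10), LHCB1.4 (0.072), GH3.3 (0.25), CYP79B3 (0.056), CYP83B1 (0.095), SOC1 (0.14), FUL (0.064) and the plastid probes (0.37), and the test of pentatricopeptide repeat genes turned down (median 0.32, camera adjusted p = 0.567); the cause was not tested. Of 120 named genes, the fold moved by over 1.5 times for 54 after median normalization, 21 with Agilent's processed signals, 10 with an offset of 10, 5 with the mean over probes, 3 with the authors' values and 3 with either array left out. Beyond those whose signs turned, none of these 120 that was past the test turned its sign, and signs of other genes were not followed. The genes whose signs turned also lost the limma call after median normalization, and a further 18 lost it there. With Agilent's processed signals 7 lost it, and 1 each did with an offset of 10, with the mean over probes and with the authors' values. The cytochrome c oxidase list passed in 7 of 11 settings and the glucosinolate list in 10, while the other 10 lists that passed did so in all 11; with an estimated correlation 0 of 24 passed in the fit reported. Lists not past in the fit reported passed camera elsewhere: abscisic acid in 4 of 11 settings (lowest adjusted p = 0.0129), copper in 3 (0.0273), jasmonate in 1 (0.0224), other respiratory subunits in 1 (0.0134), flower in 1 (0.0213) and root markers in 1 of 10 (0.0224, with a median of -0.43). The ribosomal RNA median of -0.92 was -0.68 with Agilent's processed signals, -0.22 after median normalization and -0.09 with no filter. With 1 array left, 10 of 24 list medians (without replicate 1) and 9 of 24 (without replicate 2) moved by more than the spread. That spread was the SD of the 2 array medians, which is small where the arrays agree. A list whose arrays agreed closely could thus count as moved, and one whose arrays differed as unmoved, so these counts do not measure stability. No list past the test turned its sign, while the auxin median was -0.05 for replicate 1 and 0.25 for replicate 2. Each array alone gave COX17-2 between -6.16 and -5.70 and COX17-1 between -0.57 and -0.44. Dim signal limits dim genes: 277 genes were not well above background in WT and 31 in silenced leaves.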

Other observations

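The lists in this part, and their tests, were chosen only after the result was seen, all of them after the table of all genes had been read. Of 21 expansins, which loosen cell walls, 12 rose, 1 fell and 8 did not pass, with EXLA2 at 1.29 and EXLA1 at 1.14 (median 0.48, or 0.81 after median normalization, camera adjusted p = 0.000532, and adjusted p = 0.325 with an estimated correlation). Tubulins had 13 rising, 0 falling and 2 not past of 15, with TUB7 at 1.22 (median 0.69, or 1.34 after median normalization, camera adjusted p = 1.47e-06, and adjusted p = 0.325 with an estimated correlation). Xyloglucan endotransglucosylases had 11 rising, 3 falling and 12 not past of 26, with XTH16, XTH8 (1.69) and XTH33 (1.43) leading (median 0.24, or 0.54 after median normalization, camera adjusted p = 0.00770, and adjusted p = 0.398 with an estimated correlation), and passed in 9 of 11 settings. Type-A cytokinin response regulators, which are induced by cytokinin, had 5 rising, 0 falling and 1 not past of 6, with ARR6 at 1.65 and ARR7 at 1.19 (median 0.42, or 0.97 after median normalization, camera adjusted p = 0.00225, and adjusted p = 0.398 with an estimated correlation).

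The next lists, described as 60S or 40S and as 50S or 30S, overlap the ribosomal protein list fixed beforehand. Of 219 proteins described as 60S or 40S, 171 rose, 4 fell and 44 did not pass (median 0.48, or 1.12 after median normalization, camera adjusted p = 5.29e-20, and adjusted p = 0.325 with an estimated correlation). Of 41 described as 50S or 30S, 34 rose, 3 fell and 4 did not pass, with RPL15 at 1.06 (median 0.68, or 1.34 after median normalization, camera adjusted p = 4.68e-11, and adjusted p = 0.325 with an estimated correlation). Chaperonins had 16 rising, 0 falling and 5 not past of 21, with the plastid subunits Cpn60beta2 at 1.68 and CPN60A at 1.41 (median 0.48, or 1.02 after median normalization, camera adjusted p = 9.16e-06, and adjusted p = 0.325 with an estimated correlation). Of 375 pentatricopeptide repeat genes 119 rose, 8 fell and 248 did not pass (median 0.19, camera adjusted p = 2.26e-05, and adjusted p = 0.430 with an estimated correlation), a list whose test turned after median normalization. Mitochondrial ribosomal proteins had 2 rising, 1 falling and 4 not past of 7 (median -0.03, or 0.49 after median normalization, camera adjusted p = 0.907, and adjusted p = 0.933 with an estimated correlation). Plastid-specific ribosomal proteins matched 2 genes, PSRP5 at 0.37 and PSRP6 at 0.02, and were not tested.

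Ethylene response factors were lower, with 1 rising, 14 falling and 4 not past of 19 and ERF1 (-1.84), ERF5 (-1.79), ERF-1 (-1.41) and ERF104 (-1.40) leading (median -0.75, or -0.29 after median normalization, camera adjusted p = 9.71e-08, and adjusted p = 0.325 with an estimated correlation). Of these, ERF5 and ERF104 also belong to the oxidative stress list and ERF1 to the jasmonate list. Calmodulin-like proteins had 0 rising, 4 falling and 5 not past of 9, with CML37 at -2.73 and CML41 at -2.68, and their median of -0.25 turned to 0.36 after median normalization (camera adjusted p = 0.000780, and adjusted p = 0.398 with an estimated correlation). Glutaredoxins moved both ways, with 19 rising, 13 falling and 10 not past of 42: AT4G15700 and AT4G15690 (1.79) rose while AT4G33040 (-2.33), AT2G47880 (-1.80) and GRX480 (-1.55) fell (median 0.14, or 0.67 after median normalization, camera adjusted p = 0.689, and adjusted p = 0.790 with an estimated correlation). PR1, a marker of salicylic acid signalling, was at -0.40 (limma adjusted p = 0.00386), chosen after its values were seen.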
